A study of Mus musculus with 42 samples.

How the data were processed

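Gene expression in the developing mouse prostate was measured on 42 spotted cDNA arrays in 2 colours. Per the labels, male C57BL/6J mice were taken at 7 stages: embryonic stages from E14.5 to E17.5 at daily steps, when the whole urogenital sinus was dissected, and postnatal stages P7, P30 and P90 (in days), when the ventral, anterior and dorsolateral prostate lobes were dissected and their RNA mixed in equal amounts. Each stage had 3 pools, each of 3 to 10 mice from 1 or 2 litters. Each pool was hybridised on 2 arrays with the dyes swapped, against a common reference of E14.5 urogenital sinus RNA. Pool RNA went through 1 round of linear amplification and the reference through 2 rounds, per the labels. A day of gestation that the protocol mentions after E17.5 was not analysed here. The sample titles count embryonic days differently from the descriptions, so each array took its stage and pool number from the description and stage labels.

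The deposited scanner files give intensity values, the foreground and local background medians of each spot in both channels, measured with GenePix Pro 4.0.1.17 or 4.1.1.4 without normalization in the scanner software, per the file headers. The same deposited files hold a flag for each spot that the scanner software judged bad or did not find. The deposited value table of the series gives the authors' log2 ratios, whose normalization method is not given in the sources used here. Each of its 42 columns was set against the scanner ratio of the same array, taken as pool over reference from the dye labels. Correlations ran from 0.659 to 0.992 and slopes from 0.431 to 0.985, all positive, and column medians from -0.043 to 0.031. The lowest correlation and slope were both those of E14.5 pool 3 in Cy5. The next lowest were 0.881 and 0.789, for E17.5 pool 2 in Cy5. The direction of the authors' table is therefore pool over reference and its columns are centred near 0, while its exact scale stays unknown. The submitters state that some of these normalized values were once exchanged between samples and later corrected, and that the scanner files were not affected. The scanner files were the starting point, and the authors' values served as an alternative.

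Intensities were background-corrected with normexp (saddle-point, offset 50) and normalized within each array by global loess in limma 3.58.1 under R 4.3.3, with control spots and flagged spots at weight 0 and no scaling between arrays. Every ratio was turned to pool over reference. Replicate spots of a probe were averaged, and the 2 arrays of a pool were averaged, so that the pool was the replicate (n = 3 per stage). A probe was kept where the pool channel exceeded the local background by more than 2 background SDs on at least 4 of the 6 arrays of a stage and where at least 2 pools of every stage had a value.

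Each array held 11552 spots, of which 441 were control, blank or unlabelled, and 10560 probes. Gene names came from the scanner files and can be old. They were matched to the RefSeq gene table of assembly GRCm38.p6, which was used for names only. A current symbol named 2782 probes, an older synonym 2845, and a transcript accession or gene number 69. The names of 64 probes fitted several genes and 4800 had no gene name, and neither kind was given a gene. The probe with the highest mean log2 intensity stood for each gene. Other probes of a gene did not always go the same way. Among called genes with several probes, some had a probe of the other sign. These were 1 of 7 for E17.5 minus E14.5 and 18 of 158 for P7 minus E17.5. For P30 minus P7 they were 61 of 322, and for P90 minus E14.5 74 of 516. After filtering, 10429 probes gave 9256 features, of which 4473 were named genes and 4783 unnamed probes. All features were tested, and counts in the text are of named genes. Arrays came from 2 print sets (8 arrays from the first). Reference-channel intensities correlated across positions at a median of 0.901 between the print sets and at 0.897 and 0.896 within them, and positions were treated as the same probes. Of 1061 positions with a UniGene cluster in both layouts, 958 had the same cluster number and the others did not, so for some probes the identity across print sets is less sure. All E14.5 arrays were of the first print set, so each comparison with E14.5 crosses the print sets.

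Across arrays, the median signal of the pool channel was 492 to 3853 intensity units above background (median 1504.5), and 87.6 to 98.5% of probe spots were detected in it (median 97.2%). Blank spots passed the same detection rule in 2.9 to 6.7% of cases. The number of arrays and pools limits the precision. The median standard error of a log2 difference between stages was 0.162.

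A linear model with 1 mean per stage was fitted to the 21 pools with limma (lmFit and eBayes), so that all stages shared 1 estimate of spread. The 11 contrasts were each later stage minus E14.5 and each stage minus the one before it. An F test asked whether a gene changed across stages, and the E14.5 mean was tested against 0 to compare E14.5 pools with the reference. P-values were adjusted by Benjamini-Hochberg over all 9256 features, with 0.05 as the threshold, and "passed" or "called" refers to it. Errors are SEs of the fit unless marked SD. Standard limma tests are two-sided.

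The 23 gene lists covered cell cycle, prostate secretory proteins, androgen response, endoplasmic reticulum (ER) and secretory pathway, extracellular matrix, smooth muscle, basal epithelium, luminal epithelium, urogenital sinus patterning, imprinted growth genes, immune and antigen presentation, blood, skeletal muscle, nerve and glia, endothelium, adipose, urothelium, seminal vesicle with vas and duct, ribosomal proteins, oxidative phosphorylation, cholesterol and lipid synthesis, glutathione and detoxification, and RNA processing. Lists were tested with camera (preset inter-gene correlation 0.01), adjusted over the 23 lists of a comparison. Camera with a correlation estimated from the data (limma with statmod 1.5.0) and fry were alternatives. Members passing the single-gene test were counted over all features and adjusted over the list alone. Of the 7 measured members of the seminal vesicle list, 5 are also in another list. So are 9 of 26 in the androgen response list and 6 of 19 in the prostate secretory list. Results of lists that share members are not independent. The prostate secretory list includes seminal vesicle secretory protein genes such as Svs5 and Svs6, so it does not measure prostate secretion alone.

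The stages, contrasts, lists, filters and the rule for named genes were fixed before the data were examined. In 4 main comparisons (E17.5 minus E14.5, P7 minus E17.5, P30 minus P7, P90 minus E14.5) the rule took the 10 largest rises and 10 largest falls among genes that passed and whose pools did not overlap, up to 4 passing members of each list with the largest difference, and a fixed set that included Hoxb13, Hoxd13, Shh, Pbsn, Krt5, Krt8, Trp63, Mki67, Igf2 and H19. Some genes that the rule took are not reported here. In the other comparisons it took the 2 largest in each direction. Hoxb13, Hoxd13, Krt5 and Krt8 were not measured under a matched name.

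The arrays fell on 6 days by the dates in the names of the scanner files, taken here as hybridisation days. All but 1 array were scanned on that same day, so the dates may be scan days. All E14.5 arrays and E17.5 pool 1 were on day 1 and print set 1, the other E17.5 pools on day 2, E16.5 on days 2 and 3, E15.5 on day 4, P7 on days 4 and 6, P30 on day 5, and P90 on days 5 and 6. Days link E14.5, E16.5 and E17.5 with each other, and E15.5, P7, P30 and P90 with each other, but no day links the 2 sets. Within a set the day entered an array-level fit as a fixed block. Across sets it entered as a random block, in a fit on the mean of each pool on each day. E16.5 pool 3, P7 pool 2 and P90 pool 2 had arrays on 2 days. Each therefore counted as 2 units in that fit, without a term for the pool, which overstates its number of replicates. Print set and day 1 cannot be told apart. The pool numbers are only names by their labels. Of 63 same-numbered pairs of pools, 20 had deviations from their stage means correlating over 0.1, so pools were not paired. No 2 arrays held identical intensities.

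Alternatives covered background correction, print-tip loess, median centring, scale normalization between arrays, the detection filter, the mean of all probes of a gene, each dye orientation alone, arrays as units with pool as a random block, the day, the pool number as a block, fits on only the stages compared, the authors' values, and leaving out each pool. Scale normalization and the day for the gene lists, fits on the arrays of 1 day, and fits without the 2 pools of low dye-swap correlation were added after the data were seen.

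The fits were tested on simulated data for E17.5 minus E14.5 with 200 changed genes among 4473. Apart from these, the members of the skeletal muscle list were raised by 0.5 log2. Of genes changed 1.5-fold, 38.8% were called, of those changed 2-fold 92.5%, and of those changed 4-fold 98.5%. With the day in the fit these shares were 19.4, 71.6 and 98.5%. Without the day, 161 named genes were called in this simulated comparison, 4 of them unchanged. Over 8 simulated comparisons without change, limma called 0 genes. Data handling and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.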

Results

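The series followed the mouse prostate from the urogenital sinus of the male embryo, from which prostate buds grow, to the mature gland. It held 7 stages with 3 pools each (21 pools on 42 arrays): whole urogenital sinus on each embryonic day from E14.5 to E17.5, and mixed prostate lobes at P7, P30 and P90. Age and dissected tissue changed together at birth. Each value is a log2 ratio of a pool to the common E14.5 reference, and differences between stages are differences of these ratios (n = 3 pools per stage throughout). Dye-swapped arrays of a pool correlated at a median of 0.693 across genes. The 2 lowest values were 0.173 for E16.5 pool 1 and 0.285 for E14.5 pool 3. Pools of a stage correlated at 0.68 to 0.956 (median 0.812), and E14.5 pools correlated with P90 pools at a median of 0.273.

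Over the 7 stages, 3092 of 4473 named genes (69.1%) changed by the limma F test at an adjusted p under 0.05. The first principal component held 63.5% of the variance and ran from the embryonic pools to the P90 pools, and the second (10.8%) separated P7 pools 2 and 3 from the others. Gene lists were tested 253 times (23 lists in 11 comparisons), and camera called 130 of them with its preset correlation, 83 higher and 47 lower, against 54 with an estimated correlation. When the 21 pools were assigned at random to 7 groups of 3, the preset called a median of 92 lists. The estimated correlation called a median of 0. Such mixed groups still differ in their make-up by stage, and stage differences enter their spread and so the estimated correlation. Neither median is therefore a rate by chance. The estimated correlation called fewer lists in the real groups, and its adjusted p is given beside list calls. In called lists the median, the mean and the test had the same sign.

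**Figure D1:**
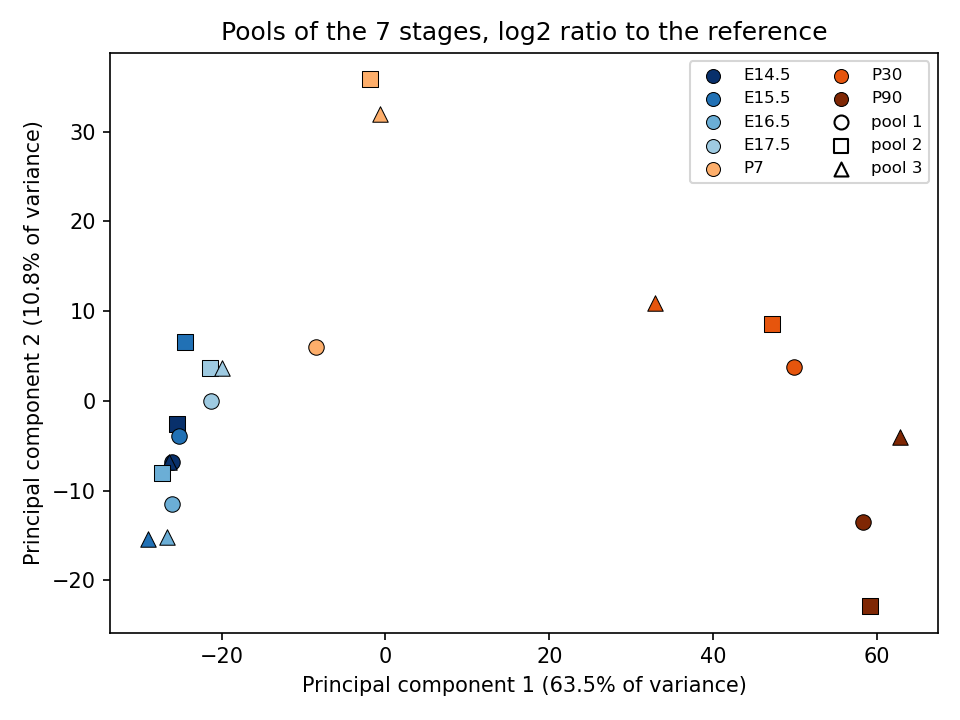
Principal components 1 (63.5% of variance, x axis) and 2 (10.8%, y axis) of the log2 ratios of the 21 pools, 1 point per pool, coloured by stage with a marker for the pool number. Embryonic pools lie between -28.97 and -19.91 on component 1, P7 pools between -8.466 and -0.7028, P30 pools between 32.88 and 49.84, and P90 pools between 58.28 and 62.78.

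Between E14.5 and E17.5, the days around the emergence of prostate buds, the largest rises were in genes of striated muscle. Mylpf, a fast skeletal myosin light chain, rose by 2.75 ± 0.38 log2 (6.75-fold, adjusted p = 0.000587). Myh3, the embryonic myosin heavy chain, rose by 2.73 ± 0.39 (adjusted p = 0.000861), and Myl4, an embryonic and atrial light chain, by 2.70 ± 0.29 (adjusted p = 7.03e-05). Tnnc2, fast skeletal troponin C, rose 5.43-fold and Tnni1, slow skeletal troponin I, 3.58-fold. Actc1 (3.27-fold) and Tnnt2 (2.98-fold), sarcomeric genes of heart and embryonic muscle, rose as well. Among other genes, Psca, a surface antigen of prostate and bladder epithelium, rose by 1.76 ± 0.24 (adjusted p = 0.000587). Nt5e, an ecto-nucleotidase, rose 3.86-fold, Aldh1a1, a retinaldehyde dehydrogenase, 2.63-fold, and Sox9, a transcription factor of growing epithelial buds, 2.09-fold. The falls were smaller. Somatostatin (Sst) was 2.16-fold lower and Crabp1, a retinoic acid binding protein, 2.04-fold lower. Rufy3, Stox2, Tenm3, Cadm1, Tgfbi and Frmd4a fell by 0.81 to 0.68 log2.

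By list, the skeletal muscle genes rose as a group: 8 of 20 measured members rose and 12 did not pass, with 16 called when adjusted over the list alone (median log2 1.13, camera adjusted p = 1.55e-33, adjusted p = 0.00113 with an estimated correlation). The list's median was 0.62 with the day in the fit (adjusted p = 5.77e-22). Both measured urothelium genes were called over the list alone and 1, Psca, over all features (camera adjusted p = 4.01e-06, adjusted p = 0.00205 with an estimated correlation). Of 9 endothelial genes, 1 rose, Kdr, the VEGF receptor (1.69-fold), and the list rose with a median of 0.21 (camera adjusted p = 0.00332, adjusted p = 0.03 with an estimated correlation). RNA processing genes fell as a group by a median of 0.14 log2, although none of the 40 passed singly in limma (camera adjusted p = 0.000109, adjusted p = 0.0069 with an estimated correlation). Among 38 cell cycle genes, whose products drive DNA replication and mitosis, none passed over all features, 1 did over the list alone, and the list's median fell by 0.23 (camera adjusted p = 1.18e-08, but adjusted p = 0.228 with an estimated correlation). Luminal epithelium (median 0.25), extracellular matrix (0.20) and smooth muscle (0.18) lists also rose with the preset correlation only, with adjusted p = 0.0609, adjusted p = 0.313 and adjusted p = 0.367 with an estimated correlation. So did immune and antigen presentation (median 0.14, adjusted p = 0.147 with an estimated correlation), androgen response (0.07, adjusted p = 0.211), ER and secretory pathway (0.07, adjusted p = 0.427) and glutathione and detoxification (0.08, adjusted p = 0.376). Markers of other tissues moved with the preset only as well, adipose higher (median 0.21, camera adjusted p = 0.0328, adjusted p = 0.335 with an estimated correlation) and nerve and glia lower (median -0.10, camera adjusted p = 0.00924, adjusted p = 0.376 with an estimated correlation), with no member of either passing over all features. Fhl1, a LIM protein of muscle, rose 1.93-fold, Cxcl12, a stromal chemokine, 1.93-fold. Itgb4, a basal integrin, rose 1.84-fold, Gsto1, a glutathione transferase, 1.84-fold, and Col6a1 1.79-fold. The preset calls of the prostate secretory list and of blood were lost with the day in the fit (adjusted p = 0.198 and adjusted p = 0.0707) and with an estimated correlation (adjusted p = 0.427 and adjusted p = 0.204). Of the fixed genes, Shh differed by 0.29 ± 0.21 and the proliferation marker Mki67 by -0.48 ± 0.26 (adjusted p = 0.871), and neither passed.

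In all, limma called 33 named genes, 25 higher and 8 lower (15 and 2 of them by 2-fold or more), with 380 at an unadjusted p under 0.05. Pools of the 2 stages did not overlap for 18.6% of genes, against 10% by chance. With median centring 25 were higher and 3 lower, and with scale normalization 110 higher and 66 lower. With the hybridisation day in the fit 25 genes were called, all higher, 16 of them among the 33. All 8 falls and the calls of Myh3 (1.88), Mylpf (1.85), Tnni1, Tnnt2, Kdr, Gsto1 and Col6a1 were lost. On day 1 alone, which held all E14.5 pools and 1 E17.5 pool, Myl4 differed by 2.07, Psca by 1.77 and Sox9 by 1.23. With the spread taken from all pools, so that the lone pool was assumed to vary like the others, 3 genes were called there, 2 of them shared. Leaving out E14.5 pools 1, 2 or 3 gave 12, 20 and 18 genes, and leaving out E17.5 pools 2 or 3 gave 21 and 19. Mylpf, Myh3, Myl4, Tnnc2, Tnni1, Actc1, Psca, Sox9, Itgb4 and Cadm1 passed without any 1 of these 6 pools.

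The muscle genes were already higher a day after E14.5. At E15.5, Myh3 was 6.44-fold (2.69 ± 0.39 log2, adjusted p = 0.00144) and Tnnc2 5.52-fold (adjusted p = 0.000608) above E14.5, while 9 of 20 skeletal muscle genes rose, with 13 higher and 1 lower when adjusted over the list alone (camera adjusted p = 5.42e-18, adjusted p = 0.0206 with an estimated correlation). The endothelium list rose too (median 0.26, camera adjusted p = 0.00147, adjusted p = 0.0354 with an estimated correlation). In all, the preset called 12 lists, all higher, and an estimated correlation only these 2. The preset-only calls included extracellular matrix (camera with an estimated correlation, adjusted p = 0.148), smooth muscle (adjusted p = 0.34), and immune and antigen presentation (adjusted p = 0.145). Nerve and glia (adjusted p = 0.421) and urothelium (adjusted p = 0.145) were others. The 2 genes that fell were Cachd1 (-0.95 ± 0.17) and Riok2 (-0.62 ± 0.14). Cachd1 did not pass without E14.5 pool 3 (-0.77) or E15.5 pool 3 (-0.80), nor did Riok2 without E14.5 pools 1 or 2 (-0.53 and -0.59) or E15.5 pools 1 or 3 (-0.65 and -0.55). In total 33 named genes were called, 31 higher and 2 lower (19 and 8 with scale normalization), with 662 at an unadjusted p under 0.05. Leaving out E14.5 pools 1, 2 or 3 gave 13, 19 and 14 genes, leaving out E15.5 pool 2 gave 84 and leaving out P7 pool 1, which enters only through the spread, gave 95. E15.5 shared no hybridisation day with E14.5, so day and stage cannot be told apart, and with the day as a random block 6 genes were called.

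At E16.5, Myh3 (5.62-fold) and Mylpf (4.32-fold) were again the largest rises over E14.5. Of 20 skeletal muscle genes, 9 rose, with 11 higher and 1 lower over the list alone (camera adjusted p = 6.05e-13, adjusted p = 0.0735 with an estimated correlation). The list's median of 0.77 was 0.36 with the day in the fit (adjusted p = 0.0455). It was 1 of 9 lists called with the preset correlation, all higher, and an estimated correlation called 0. Prmt1, an arginine methyltransferase, was 4.31-fold lower (-2.11 ± 0.31, adjusted p = 0.00129) and Sh3d19, an adaptor protein, 3.02-fold lower. Named genes called numbered 181, 90 higher and 91 lower. With the day in the fit, which E17.5 links between these stages, Myh3 (1.25) and Mylpf (0.70) did not pass and 1 gene was called. Without the 2 pools of low dye-swap correlation 5 were called. Without E14.5 pools 1, 2 or 3 the counts were 56, 74 and 60, without E16.5 pools 1 or 2 they were 68 and 49, and without P7 pool 1 the count was 304. Genes higher in all 3 later embryonic stages than at E14.5 numbered 13: Myl4, Mylpf, Myh3, Tnnc2, Tnni1, Tnnt2, Actc1, Psca, Penk, Ramp1, Gadd45g, Mxra8 and Cited2, some of which fall outside the rule for named genes and were named after their values were seen. Of these, 7 were in the skeletal muscle list. Independent lists would share 0.00985 genes, a value that leaves out the shared E14.5 pools, to which part of the excess may be due. Unchanged groups simulated against those pools shared 0, but with no effect a test adjusted over all features makes few calls by design, so that value does not measure their part.

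From E15.5 to E16.5, Calr, an ER chaperone, rose 2.13-fold (adjusted p = 0.0141) and Smim15 1.88-fold, while Sh3d19 was 2.84-fold lower (-1.51 ± 0.28, adjusted p = 0.0191) and Atxn7l3b 2.17-fold lower. The extracellular matrix list fell (3 of 43 fell, 7 over the list alone, median -0.25, camera adjusted p = 7.67e-06, adjusted p = 0.592 with an estimated correlation). Limma called 18 named genes, 3 higher and 15 lower, with 552 at an unadjusted p under 0.05, and 0 with the day as a random block. Pools did not overlap for 16.1% of genes, against 10% by chance. With the pool in Cy3 alone 358 were called, and in Cy5 alone 45. The split was 11 higher and 27 lower with print-tip loess, 1 and 16 with median centring, 3 and 8 with scale normalization, and 16 and 26 in the authors' values. The count was 0 without E15.5 pool 2 or without E16.5 pool 1, 10 and 38 without E15.5 pools 1 and 3, 6 without E16.5 pool 2 and 51 without P7 pool 1.

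From E16.5 to E17.5, Sh3d19 (3.96-fold, 1.99 ± 0.28, adjusted p = 0.00147) and Prmt1 (3.26-fold) rose back, and Agtr2, an angiotensin receptor of fetal mesenchyme (-1.48 ± 0.27), and Stmn2, a neuronal stathmin (-1.29 ± 0.32), fell. Nerve and glia markers fell with the preset correlation: 4 of 12 fell, 7 over the list alone (median -0.65, camera adjusted p = 4.85e-05, adjusted p = 0.582 with an estimated correlation). The other 3 list calls were lower with the preset only, and few of their members passed singly. In the cell cycle list 1 of 38 genes passed and it was higher, against a median of -0.20 (camera adjusted p = 0.0035, adjusted p = 0.871 with an estimated correlation). In oxidative phosphorylation 1 of 49 was lower (median -0.21, camera adjusted p = 2.3e-05, adjusted p = 0.582 with an estimated correlation). In ribosomal proteins 1 of 59 was higher and 1 lower (median -0.10, camera adjusted p = 0.00463, adjusted p = 0.629 with an estimated correlation, adjusted p = 0.0629 with the day). Called were 202 named genes, 106 higher and 96 lower. With the day in the fit 164 were called, 110 of them shared, and on day 2 alone 21, 20 of them shared. Prmt1 did not pass without E16.5 pool 2 (1.30) or E17.5 pool 2 (1.60), nor did Stmn2 without E16.5 pools 1 or 2 (-1.26 and -1.27) or E17.5 pools 1, 2 or 3 (-1.25, -1.40 and -1.22). The count fell to 53 and 14 without E16.5 pools 1 and 2, to 15 and 35 without E17.5 pools 2 and 3, and to 36 without the 2 pools of low dye-swap correlation, and it was 352 without P7 pool 1.

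Between E17.5 and P7, across birth and the change from whole sinus to dissected lobes, smooth muscle genes had the largest rises. Tagln (transgelin) rose by 3.00 ± 0.28 log2 (8.02-fold, adjusted p = 4.53e-07) and Myh11, the smooth muscle myosin heavy chain, by 2.99 ± 0.23 (adjusted p = 6.27e-08). Acta2, smooth muscle actin, rose by 2.26 ± 0.18 and Tpm2, a tropomyosin, by 2.29 ± 0.20. Agr2, a disulfide isomerase of secretory epithelium, rose 5.33-fold, Cpxm2, a carboxypeptidase-like secreted protein, 5.20-fold. The flavin monooxygenases Fmo2 and Fmo1 rose 6.19-fold and 4.69-fold, Trpc2 4.71-fold and H2-K1, an MHC class I heavy chain, 4.36-fold. The uroplakin Upk1b fell most (-2.47 ± 0.22, adjusted p = 2.62e-07), followed by Psca (-2.08 ± 0.24) and osteopontin, Spp1 (-2.08 ± 0.25). Lrrn1, Hbb-b1 (adult beta globin), Col23a1, 6330403K07Rik, Myh3, Id3, a BMP target, and Skp2, a cell cycle ubiquitin ligase subunit, were 3.73-fold to 3.03-fold lower. Pbsn (0.37 ± 0.39), Trp63 (0.07 ± 0.11) and Shh (-0.02 ± 0.21) did not pass. Mki67 (-0.69 ± 0.26, adjusted p = 0.096) did not pass either.

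Of 20 smooth muscle genes, 14 rose and 6 did not pass, with 15 higher and 1 lower over the list alone (median 0.97, camera adjusted p = 3.95e-17, adjusted p = 0.00445 with an estimated correlation). Immune and antigen presentation genes rose, 8 of 20 over all features and 9 over the list alone (camera adjusted p = 2.41e-09, adjusted p = 0.0036 with an estimated correlation). Ifitm3 (4.29-fold) and Ly6e (3.29-fold), both interferon-inducible, were among them. Glutathione and detoxification genes rose, 8 of 31 with 1 lower, and 11 higher and 2 lower over the list alone (camera adjusted p = 1.56e-06, adjusted p = 0.0417 with an estimated correlation). The metallothioneins Mt2 (4.16-fold) and Mt1 (2.90-fold) and Gstm2 (2.89-fold) led them. Both urothelium genes fell (camera adjusted p = 8.6e-06, adjusted p = 0.0036 with an estimated correlation). All 3 globin genes of the blood list fell, including the embryonic Hbb-bh1 (-0.92 ± 0.25, not passing at -0.82 without E17.5 pool 2 or -0.95 without P7 pool 2; camera adjusted p = 0.00215, adjusted p = 0.0417 with an estimated correlation). Urogenital sinus patterning genes fell, 16 of 37 with 3 higher, and 17 lower and 5 higher over the list alone (camera adjusted p = 0.000416, adjusted p = 0.0351 with an estimated correlation). Wnt4 (-1.45 ± 0.26) and Crabp1 (-1.33 ± 0.21) were among the falls.

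Among the other lists, 18 of 59 ribosomal protein genes rose, 26 over the list alone (camera adjusted p = 1.85e-07, adjusted p = 0.0639 with an estimated correlation), as did 18 of 49 oxidative phosphorylation genes, 27 over the list alone (camera adjusted p = 8.29e-11, adjusted p = 0.051 with an estimated correlation). Luminal epithelium genes rose in 11 of 26 cases and fell in 2 (camera adjusted p = 0.000621, adjusted p = 0.0856 with an estimated correlation). Among them were Tspan1 (2.76-fold), Spint2 (2.41-fold) and Cldn10 (2.31-fold). Imprinted growth genes fell, 4 of 13 with 1 higher, led by the growth inhibitor Cdkn1c (-1.59 ± 0.24) and the growth factor Igf2 (-1.07 ± 0.20; camera adjusted p = 0.0105, adjusted p = 0.051 with an estimated correlation). Cell cycle genes fell, 4 of 38, with Mcm3 (-0.90 ± 0.21) the largest (camera adjusted p = 0.003, adjusted p = 0.477 with an estimated correlation). P7 pools 2 and 3 carried this fall, with list means of -0.765 and -0.658. P7 pool 1, at -0.156, lay within the E17.5 pools (-0.337 to -0.124). Extracellular matrix genes went both ways, 12 of 43 higher, such as Mfap5 (3.87-fold), Fmod (2.62-fold) and Col1a1 (2.56-fold), and 5 lower, such as Lox (-1.41 ± 0.24). The list was called higher with a median of 0.18 (camera adjusted p = 0.0313, adjusted p = 0.499 with an estimated correlation, adjusted p = 0.0629 with the day). With scale normalization it was called lower instead, with a median of -0.23 (camera adjusted p = 0.005275). The prostate secretory call (median 0.42, camera adjusted p = 0.0108) was lost with an estimated correlation (adjusted p = 0.418) and with the day (adjusted p = 0.126). Skeletal muscle genes, markers of another tissue, divided into 6 higher, such as Tnnc2 (1.23 ± 0.32, but -0.23 with scale normalization), and 5 lower. Myh3 (-1.70 ± 0.39) and Tnni1 (-1.23 ± 0.30) were among the lower. The list did not pass, with a median of 0.31. With scale normalization it was called lower, with a median of -0.21 (camera adjusted p = 0.01198). In the androgen response list, 3 of 26 rose and 3 fell, and in the nerve and glia list Nefl, neurofilament light chain, was 2.88-fold lower. Single pools decided some of these calls. Mcm3 did not pass without P7 pool 2 (-0.71), Myh3 without E17.5 pool 3 (-1.41), Tnni1 without E17.5 pools 2 or 3 (-1.11 and -0.95), Tnnc2 without E17.5 pool 1 (0.94) or P7 pool 1 (0.90), or Nefl without E17.5 pool 2 (-1.33) or P7 pool 3 (-0.97).

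In total 654 named genes were called, 340 higher and 314 lower (94 and 60 by 2-fold or more), and pools did not overlap for 30.1% of genes, against 10% by chance. No hybridisation day held both stages, so day and stage cannot be told apart directly, and with the day as a random block 451 genes were called, 440 of them shared. P7 pool 1 correlated at 0.692 and 0.68 with pools 2 and 3, which correlated at 0.912 with each other. Without P7 pool 1 the count was 1149, without P7 pool 2 332, and without E17.5 pools 2 or 3 it was 359 and 373. Against E14.5, P7 had 1303 genes called, 663 higher and 640 lower, led by Tnnc2 (12.8-fold) and Tagln (11.9-fold) among the rises and Hbb-b1 (6.69-fold lower) and Nefl (6.31-fold lower) among the falls. The skeletal muscle list was higher (13 of 20 higher, camera adjusted p = 7.05e-11, adjusted p = 0.0411 with an estimated correlation) and so was smooth muscle (14 of 20 higher, 1 lower, adjusted p = 0.0144 with an estimated correlation). That count was 819 without E14.5 pool 3, 784 without P7 pool 2, and 863 with the day as a random block, 859 of them shared.

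**Figure D2:**
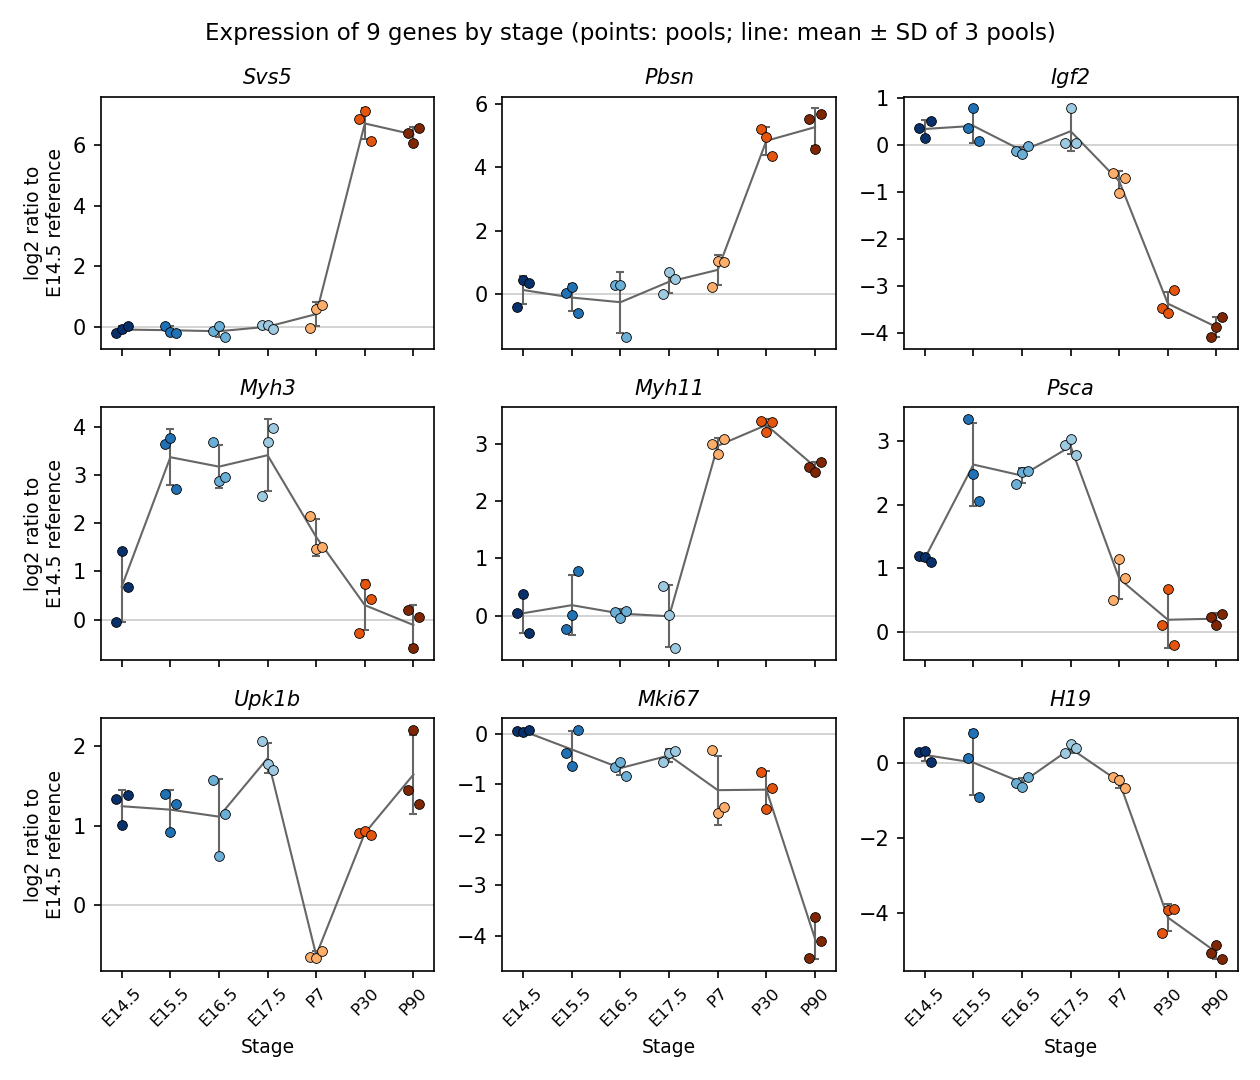
Log2 ratio to the E14.5 reference (y axis) of 9 genes at the 7 stages (x axis), with 1 point per pool and a line through the stage means with SD bars (n = 3 pools). Myh3 rises after E14.5, Myh11 at P7, Svs5 and Pbsn at P30 (78.1-fold and 16.8-fold above P7), Upk1b and Psca are lower at P7 than at E17.5, H19 falls by 3.64 from P7 to P30, and Mki67 falls by 2.94 from P30 to P90.

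Between P7 and P30, genes of secreted proteins had the largest rises. Svs5 and Svs6, seminal vesicle secretory protein genes, rose by 6.29 ± 0.21 log2 (78.1-fold, adjusted p = 4.65e-15) and 5.52 ± 0.48 (45.7-fold, adjusted p = 2.57e-08). Without P30 pool 3 the rise of Svs6 was 81.6-fold. Sbp, the spermine binding protein, rose 20.1-fold, and Tgm4, the prostate transglutaminase of the copulatory plug, 16.9-fold. Apof, apolipoprotein F, rose by 4.09 log2 (4.69 without P30 pool 3) and Pbsn, the androgen-regulated probasin, by 4.07 ± 0.39 (16.8-fold, adjusted p = 9.22e-08). Uba7, a ubiquitin-like activating enzyme, 9530002B09Rik, the protease inhibitor Spink5 and the complement protease C1ra rose 16.5-fold to 14.0-fold. The largest falls were in the noncoding H19 (-3.64 ± 0.27, adjusted p = 2.20e-09), which is imprinted, and in Capn6, a calpain-like protein (-3.22 ± 0.17). Next came the imprinted genes Peg3 (-2.83 ± 0.28), Igf2 (-2.61 ± 0.20) and Meg3 (-2.57 ± 0.23), then Lpin3 (-2.53 ± 0.16) and the imprinted Cdkn1c (-2.40 ± 0.24). Marcksl1 (-2.29 ± 0.24), Cdx2, a hindgut homeobox gene (-2.21 ± 0.27), and the transcription factor Sox4 (-2.16 ± 0.20) followed. Trp63, the basal cell transcription factor, rose by 0.57 ± 0.11 (adjusted p = 0.000708, lost with the day in the fit). Neither Shh (-0.18 ± 0.21) nor Mki67 (0.01 ± 0.26) passed.

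By list, 16 of 19 prostate secretory genes rose and 3 did not pass, with 17 higher and 1 lower over the list alone (median 2.77, camera adjusted p = 7.95e-15, adjusted p = 0.0134 with an estimated correlation). Seminal vesicle, vas and duct markers moved with them, 5 of 7 higher, including Svs4 (9.05-fold) and Pate4 (8.24-fold), with a median of 3.04 (camera adjusted p = 2.42e-07, adjusted p = 0.0134 with an estimated correlation). Of these 7, 5 are also in another list. The rises of these lists do not tell prostate from seminal vesicle tissue as the source, which was not tested. ER and secretory pathway genes rose, 28 of 51 with 3 lower, and 31 higher and 4 lower over the list alone (camera adjusted p = 6.14e-09, adjusted p = 0.04 with an estimated correlation). The signal peptidase subunit Sec11c (5.63-fold), the cargo receptor Tmed3 (5.15-fold), Herpud1 (5.00-fold) and the chaperone Hspa5 (4.15-fold, and 6.52-fold without P7 pool 1) led them. Androgen response genes rose, 10 of 26 with 3 lower, among them the protease Tmprss2 (5.29-fold) and sorbitol dehydrogenase, Sord (3.98-fold; camera adjusted p = 0.000373, adjusted p = 0.04 with an estimated correlation). Luminal epithelium genes rose, 15 of 26 with 3 lower, led by the claudins Cldn10 (4.90-fold) and Cldn8 (3.71-fold) and the keratin Krt19 (3.32-fold; camera adjusted p = 5.64e-05, adjusted p = 0.04 with an estimated correlation). Immune and antigen presentation genes rose, 10 of 20 with 2 lower (camera adjusted p = 0.000785, adjusted p = 0.04 with an estimated correlation). They included complement C3 (5.48-fold), the class I light chain B2m (5.13-fold), H2-K1 (4.69-fold) and Psmb8 (3.54-fold). Glutathione and detoxification genes rose, 15 of 31 with 1 lower, led by the peroxiredoxin Prdx5 (10.3-fold) and the aldose reductase Akr1b3 (5.21-fold; camera adjusted p = 6.94e-06, adjusted p = 0.04 with an estimated correlation).

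Extracellular matrix genes fell, 24 of 43 with none higher and 29 over the list alone (camera adjusted p = 1.89e-12, adjusted p = 0.04 with an estimated correlation). Fibrillin 2, Fbn2 (-2.08 ± 0.18), versican, Vcan (-1.92 ± 0.23), Col3a1 (-1.53 ± 0.34) and Col1a1 (-1.31 ± 0.19) were among them. Imprinted growth genes fell, 8 of 13 with 1 higher (median -0.63, camera adjusted p = 1.23e-05, adjusted p = 0.0121 with an estimated correlation). Urogenital sinus patterning genes fell, 20 of 37 with 6 higher (camera adjusted p = 0.000629, adjusted p = 0.04 with an estimated correlation). Sox4 and the Wnt inhibitor Sfrp2 (-1.51 ± 0.16) were among the falls and Crabp1 (11.4-fold) and Foxa2 (2.86-fold) among the rises. RNA processing genes fell, 12 of 40, including Hnrnpa0 (-1.20 ± 0.14) and Hnrnpd (-1.14 ± 0.20; camera adjusted p = 0.000593, adjusted p = 0.0155 with an estimated correlation). Cell cycle genes fell, 16 of 38 with 19 over the list alone, including the replication helicase subunits Mcm4 (-1.06 ± 0.20) and Mcm5 (-1.05 ± 0.27, not passing at -0.78 without P30 pool 2; camera adjusted p = 1.05e-06, but adjusted p = 0.221 with an estimated correlation). Nerve and glia markers fell, 7 of 12, such as Fabp7 (-1.43 ± 0.18) and Stmn2 (-1.29 ± 0.32, lost with the day in the fit and at -0.88 without P30 pool 1; camera adjusted p = 0.000112, adjusted p = 0.18 with an estimated correlation). The skeletal muscle list did not pass (5 of 20 lower, median -0.46, camera adjusted p = 0.0597), nor did smooth muscle (2 higher and 2 lower of 20). Basal epithelium had 1 higher, Trp63, and 4 lower, among them Jag1 (-0.97 ± 0.17) and Cdh3 (-0.70 ± 0.13).

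Of 1396 named genes called, 624 were higher and 772 lower (198 and 137 by 2-fold or more), and pools did not overlap for 40.8% of genes, against 10% by chance. With the day in the fit 807 genes were called, 695 of them shared. P7 and P30 shared no day and were linked only through P90. Without P30 pool 1 the count was 897.

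**Figure D3:**
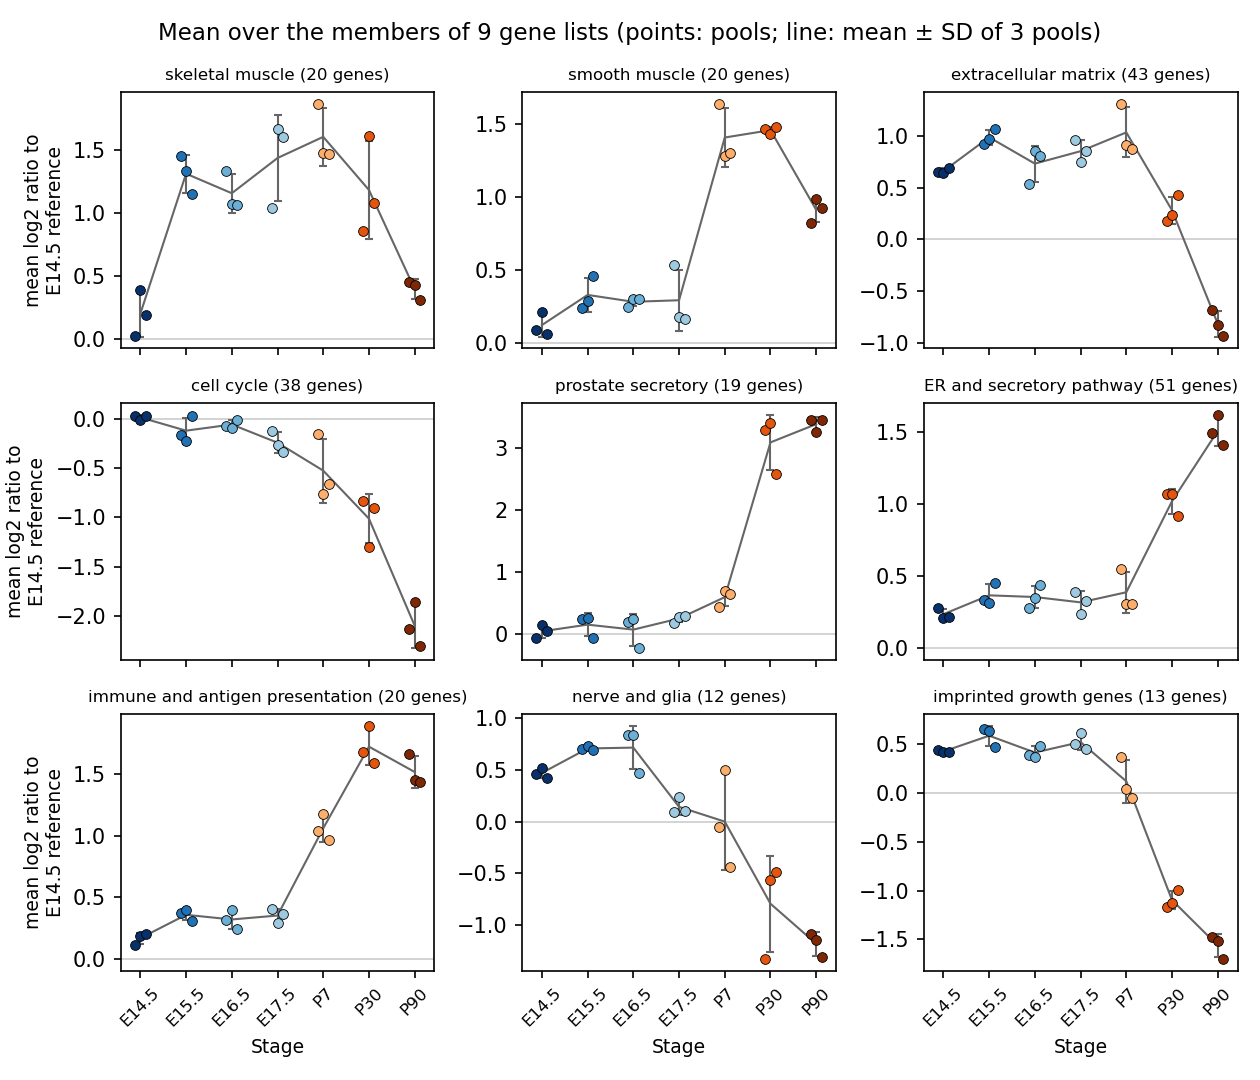
Mean log2 ratio to the E14.5 reference over the measured members of 9 gene lists (y axis) at the 7 stages (x axis), with 1 point per pool and a line through the stage means with SD bars (n = 3 pools). Skeletal muscle means lie between 0.026 and 0.392 in E14.5 pools and between 1.04 and 1.67 in E17.5 pools, prostate secretory genes are higher at P30 than at P7, and cell cycle and extracellular matrix genes are lower at P90 than at P30.

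From P30 to P90, matrix and proliferation genes fell. Col1a1, a chain of type I collagen, fell by 3.60 ± 0.19 log2 (12.1-fold, adjusted p = 4.47e-11) and Mki67 by 2.94 ± 0.26 (7.70-fold, adjusted p = 1.17e-07). Akr1b7, an aldo-keto reductase, rose by 2.63 ± 0.47 (adjusted p = 0.000699, 3.47 without P30 pool 3) and Hcfc2, a host cell factor, by 2.62 ± 0.22. In the cell cycle list 30 of 38 genes fell and 8 did not pass, with 33 called over the list alone (median -1.10, camera adjusted p = 7.35e-27, adjusted p = 0.0312 with an estimated correlation). In the extracellular matrix list 26 of 43 fell, 32 over the list alone (median -0.81, camera adjusted p = 7.35e-27, adjusted p = 0.0245 with an estimated correlation). ER and secretory pathway genes rose, 24 of 51 with none lower and 29 over the list alone (median 0.49, camera adjusted p = 1.10e-12, adjusted p = 0.0305 with an estimated correlation). Urogenital sinus patterning genes fell, 11 of 37 (camera adjusted p = 0.000167, adjusted p = 0.0305 with an estimated correlation). Smooth muscle (11 of 20 lower) and skeletal muscle (9 of 20 lower) fell with the preset correlation, each with adjusted p = 0.0698 with an estimated correlation. Imprinted growth genes (5 of 13 lower, median -0.38, camera adjusted p = 0.0202, adjusted p = 0.0698 with an estimated correlation) were called with the preset only as well. So were 4 lists whose calls were also lost with the day in the fit. RNA processing was lower (6 of 40 lower and 1 higher, median -0.20, adjusted p = 0.0698 with an estimated correlation), as were nerve and glia (2 of 12 lower, median -0.33, adjusted p = 0.402) and basal epithelium (2 of 8 lower, median -0.22, adjusted p = 0.116, all with an estimated correlation). Luminal epithelium was higher (6 of 26 higher and 1 lower, median 0.21, adjusted p = 0.261 with an estimated correlation). Limma called 686 named genes, 291 higher and 395 lower, against 347 and 313 with median centring and 42 and 128 with scale normalization. With the day in the fit 610 were called, 461 of them shared, and on day 5 alone, which held both stages, 629 were called, 450 of them shared. Without P30 pool 3 the count was 388.

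Over the whole course, from E14.5 to P90, secretory genes again led. Svs5 (86.2-fold, 6.43 ± 0.21, adjusted p = 2.03e-15), epidermal growth factor, Egf (77.0-fold), Svs6 (66.7-fold, and 103-fold without P90 pool 3), Spink5 (63.4-fold), Agr2 (62.1-fold), C1ra (56.1-fold), Tgm4 (49.1-fold), Prdx5 (40.9-fold), Pbsn (35.1-fold, 5.13 ± 0.39) and Sbp (34.9-fold) had the largest rises. H19 (-5.29 ± 0.27, 39.1-fold lower, adjusted p = 1.19e-12), Fbn2 (-5.16 ± 0.18), Capn6 (-4.92 ± 0.17), Meg3 (-4.72 ± 0.23), Cdkn1c (-4.66 ± 0.24), Hbb-b1 (-4.52 ± 0.33), 6330403K07Rik (-4.27 ± 0.23), Cdx2 (-4.25 ± 0.27), Nefl (-4.23 ± 0.38) and Igf2 (-4.23 ± 0.20) had the largest falls. Mki67 was 17.2-fold lower (-4.10 ± 0.26, adjusted p = 3.19e-11). Trp63 (0.00 ± 0.11) and Shh (-0.25 ± 0.21) did not pass.

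Of the lists that rose, 16 of 19 prostate secretory genes were higher and 1 lower (median 3.73, adjusted p = 0.011 with an estimated correlation), as were 44 of 51 ER and secretory pathway genes with 1 lower (median 1.16, adjusted p = 0.0069) and 21 of 26 luminal epithelium genes with 2 lower (median 1.61, adjusted p = 0.0084, all with an estimated correlation). Also higher were 16 of 20 immune and antigen presentation genes with 1 lower (median 1.11, adjusted p = 0.0069), 24 of 31 glutathione and detoxification genes with 4 lower (median 0.93, adjusted p = 0.0105) and 6 of 7 seminal vesicle, vas and duct genes with 1 lower (median 3.02, adjusted p = 0.0264, all with an estimated correlation). Examples were Cldn10 (27.6-fold), Sec11c (23.5-fold), B2m (19.3-fold), Mt1 (16.6-fold) and Herpud1 (14.8-fold). Of those that fell, 35 of 38 cell cycle genes were lower (median -2.22, adjusted p = 0.0243), as were 32 of 43 extracellular matrix genes with 2 higher (median -1.50, adjusted p = 0.0274), 23 of 37 urogenital sinus patterning genes with 4 higher (median -1.05, adjusted p = 0.00557, all with an estimated correlation). Also lower were 7 of 13 imprinted growth genes (median -0.60, adjusted p = 0.00557) and 26 of 40 RNA processing genes with 4 higher (median -0.59, adjusted p = 0.00428, all with an estimated correlation). Birc5 (-3.69 ± 0.23), Mfap4 (-3.55 ± 0.18), Mcm3 (-3.52 ± 0.21), the hedgehog receptor Ptch1 (-2.83 ± 0.25) and Hnrnph1 (-1.88 ± 0.17) were among the falls. Adjusted over the list alone, the counts of calls in either direction were 17, 45, 24, 17, 28 and 7 for the lists that rose, and 37, 36, 28, 7 and 32 for those that fell, in the same order.

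Calls with the preset correlation only were androgen response (15 of 26 higher, 5 lower, adjusted p = 0.0536 with an estimated correlation), smooth muscle (12 of 20 higher, 2 lower, adjusted p = 0.172), nerve and glia (10 of 12 lower, adjusted p = 0.126), adipose (4 of 8 higher, adjusted p = 0.183) and oxidative phosphorylation (19 of 49 higher, 2 lower, adjusted p = 0.314). Their examples were Tmprss2 (10.2-fold), Tagln (10.9-fold), Stmn2 (-4.01 ± 0.32), Cfd, the adipocyte protease adipsin (10.5-fold, but 5.89-fold without P90 pool 1 and 21.4-fold without P90 pool 3), and Ndufa1 (3.70-fold). Lists that did not pass were skeletal muscle (5 of 20 higher, 1 lower, median -0.02), basal epithelium (2 of 8 higher, 4 lower, such as Sfn with -1.68 ± 0.17), blood (2 of 3 lower), endothelium (1 of 9 higher, 3 lower), urothelium (1 of 2 lower), ribosomal proteins (12 of 59 higher, 4 lower) and cholesterol and lipid synthesis (3 of 13 higher, 4 lower). Named genes called numbered 2269 of 4473 (50.7%), 1064 higher and 1205 lower (467 and 526 by 2-fold or more). Pools did not overlap for 57.9% of genes, against 10% by chance. With the day as a random block 1978 were called, 1969 of them shared. At P30 the corresponding count against E14.5 was 1965, 904 higher and 1061 lower, led by Svs5 (111-fold) and Svs6 (57.9-fold, and 103-fold without P30 pool 3) above, and by H19 (20.5-fold lower) and Hbb-b1 (-4.00 log2) below. With the day it was 1520, all shared. These stages shared no day with E14.5. Against E15.5, which day 4 linked to P7 and through it to P30 and P90, the fit with the day called 385 of the 1303 genes at P7, 837 of the 1965 at P30 and 1308 of the 2269 at P90. These comparisons share the later pools, so they are not independent.

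Genes that moved before birth were followed after it. Of the 33 genes called between E14.5 and E17.5, 14 (42.4%) moved in the same direction between P7 and P90, against 48.6% of all genes (permutation of genes, p = 0.601, two-sided). Of the 25 that rose, 18 were lower at P90 than at P7, and of the 8 that fell, 1 was higher. Across genes, which are not independent replicates, the E17.5 and P90 differences from E14.5 correlated at 0.349 with a covariance of 0.0931. Unchanged groups simulated against the same E14.5 pools gave a correlation of 0.5 and a covariance of 0.0169, a difference of covariance of 0.0762.

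The E14.5 pools were also set against the reference, RNA of the same stage and tissue that had 1 more round of amplification. By limma 1152 named genes differed from it, 727 higher and 425 lower in the pools, with a median absolute log2 ratio of 0.487, against 0.185 over all named genes, and 89 differed by 2-fold or more. Psca, for one, stood at 1.11 to 1.19 in the 3 E14.5 pools. Without E14.5 pools 2 or 3 the count was 680 and 586, and with the day in the fit 601. Differences between stages do not contain this offset, since every pool was set against the same reference.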

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

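Signal and detection of single arrays were compared within the 6 arrays of each stage, in 28 groups of values. A value stood far from the nearest other in 7 of them, where chance alone would give about 1.4. In the pool channel, E14.5 pool 2 in Cy3 had a median signal of 3853 intensity units over background (nearest array 2306) and E15.5 pool 1 in Cy3 3445 (nearest 1864). Detection in the pool channel was low in 3 arrays with the pool in Cy5: E14.5 pool 1 with 91.8% of probe spots (nearest 97.2%), P7 pool 3 with 87.6% (nearest 96%) and P90 pool 2 with 88.8% (nearest 97%). On the array of E14.5 pool 1 in Cy5 the reference channel was low too, at 92.7% (nearest 96.7%). The scanner software marked 2.28% of spots as bad on the array of E17.5 pool 3 in Cy3, against 1.31% on the nearest array.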

How the results depend on the processing

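The day and scale normalization in list tests, fits on the arrays of 1 day, and fits without the 2 pools of low dye-swap correlation were chosen only after the results were seen. Direction was compared only where a gene was called in the main fit or in the alternative. A change of sign in a gene called in neither was counted as kept. Of 329 gene results under 5305 alternatives, 4968 were kept by this rule, 329 lost the call, 4 gained it and 4 changed sign. Leaving out single pools (1974 alternatives) kept 1744, ended 229, gave 1 and turned 0. With scale normalization Dcn (-0.60), Itgb4 (-0.035) and Tnnc2 (-0.23) turned negative between E17.5 and P7. So did the medians of the extracellular matrix (-0.23, camera adjusted p = 0.005275) and skeletal muscle (-0.21, camera adjusted p = 0.01198) lists, both called lower there. Adipsin, Cfd, turned to -0.43 between P7 and P30 with the day in the fit. The cause was not tested for any change given here, unless fewer pools or arrays were used. Of 92 list results, an estimated correlation ended 26 calls, fry 14 (and gave 9), scale normalization 5, and the day 4. Over all 11 comparisons camera called 54 lists with an estimated correlation against 130, and fry, which does not compare a list with other genes, called 112.

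Counts that moved by more than 1.5 times follow, with the main count first. For E15.5 minus E14.5 (33), the count was 12 with the pool in Cy3, 52 with the authors' values, 139 with arrays as units, 6 with the day, 86 with only the stages compared and 11 without the 2 pools. For E16.5 minus E14.5 (181), it was 338 with scale normalization, 34 in Cy3, 295 with arrays as units, 1 with the day, 398 with only the stages compared and 5 without the 2 pools. For E17.5 minus E14.5 (33), it was 176 with scale normalization, 21 in Cy3, 11 in Cy5, 52 with arrays as units, 147 with only the stages compared, 21 without the 2 pools and 3 on day 1. For P7 minus E14.5 (1303), it was 537 in Cy5, 863 with the day and 761 without the 2 pools. For E16.5 minus E15.5 (18, and 552 at an unadjusted p under 0.05), limma gave 38 with print-tip loess, 11 with scale normalization, 358 in Cy3, 45 in Cy5, 42 with the authors' values and 55 with arrays as units. It gave 0 with the day, 0 with only the stages compared and 0 without the 2 pools. For E17.5 minus E16.5 (202), the count was 489 with scale normalization, 67 in Cy3, 20 in Cy5, 315 with the authors' values, 353 with arrays as units, 510 with only the stages compared, 36 without the 2 pools and 21 on day 2. For P7 minus E17.5 (654), it was 230 in Cy5 and 332 with only the stages compared. For P30 minus P7 (1396), it was 917 in Cy3, 791 in Cy5 and 807 with the day. For P90 minus P30 (686), it was 170 with scale normalization and 369 in Cy3. For E14.5 pools against the reference (1152), it was 1920 with scale normalization, 678 in Cy5, 601 with the day and 544 without the 2 pools.

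Leaving out each pool in turn gave 13 to 95 genes for E15.5 minus E14.5, 49 to 304 for E16.5 minus E14.5, 12 to 43 for E17.5 minus E14.5, 784 to 1767 for P7 minus E14.5, 1660 to 2137 for P30 minus E14.5 and 2057 to 2388 for P90 minus E14.5. The ranges were 0 to 51 for E16.5 minus E15.5, 14 to 352 for E17.5 minus E16.5, 332 to 1149 for P7 minus E17.5, 897 to 1687 for P30 minus P7 and 388 to 864 for P90 minus P30. Across stages the range was 2883 to 3473, and against the reference 586 to 1365. The highest counts came without P7 pool 1. The lowest came without E14.5 pool 1 for E15.5, E17.5 and P90 minus E14.5, without E16.5 pool 2 for E16.5 minus E14.5 and E17.5 minus E16.5, and without P7 pool 2 for P7 minus E14.5 and P7 minus E17.5.

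With the pool number as a block, 30 genes were called for E17.5 minus E14.5, 640 for P7 minus E17.5, 1356 for P30 minus P7, 2252 for P90 minus E14.5 and 3041 across stages, and no count of genes or lists moved by more than 1.5 times. Same-numbered pools had deviations correlating from -0.374 to 0.502 (median 0.00962), 20 of 63 pairs over 0.1, and 7 of 21 pools were closest to their own number. The median log2 difference of all features had an absolute value of at most 0.0553 over all comparisons and settings. In the simulated E17.5 minus E14.5 comparison 38.8% of genes changed 1.5-fold were called, and 19.4% with the day in the fit. The simulated noise was independent between arrays, without an effect of day or print set. There 161 genes were called, against 33 in the real comparison. So these shares set no limit of detection for the real data or the other comparisons.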

Other observations

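Tests chosen only after the result was seen are those of the list calls with an estimated correlation over random groups, both on skeletal muscle, those on the day and pool 1 of E16.5, and all 3 on P7 pool 1. Outside the skeletal muscle list, 6 genes were higher at every later embryonic stage than at E14.5. Penk, the proenkephalin gene, was higher by 1.37, 1.15 and 1.15 log2 at E15.5, E16.5 and E17.5, and Ramp1, a receptor activity modifying protein, by 1.44, 1.44 and 0.97. Psca was higher by 1.47, 1.30 and 1.76, Mxra8 by 0.82, 0.55 and 0.88, Gadd45g by 0.78, 0.65 and 0.84, and Cited2 by 0.72, 0.71 and 0.67. Penk, Ramp1, Mxra8, Gadd45g and Cited2 were chosen after their values were seen. Part of these shared rises may come from the shared E14.5 pools. With the day in the fit 1 gene was called at E16.5 against E14.5.

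Skeletal muscle genes were higher in the 9 later embryonic pools than in the E14.5 pools. The lowest later pool exceeded the highest E14.5 pool by 0.651 in the mean over the list. The SD between pools of a stage was 0.223. Skeletal muscle carried along in some later dissections only would leave some later pools low, which was not seen. This test was chosen after the result and restates the pattern. More skeletal muscle in every later dissection than at E14.5 stays open, untested. The hybridisation day and print set stay open: with the day in the fit the list stayed higher, but its median went from 1.13 to 0.62 at E17.5 (adjusted p = 5.77e-22) and from 0.77 to 0.36 at E16.5 (adjusted p = 0.0455). These are preset calls, the one at E16.5 was lost with an estimated correlation without the day (adjusted p = 0.0735), and only E17.5 pool 1 ties the E14.5 day to the others. In that pool the 8 called members were a median of 1.65 above the E14.5 pools, all 8 above each of them. Over the 3 E17.5 pools the median was 2.14. These members were called in a comparison that held the same pools, so part of their rise is built in. The mean over the whole list was 1.043 in E17.5 pool 1, the lowest of the 9 later embryonic pools. It was 1.666 and 1.604 in E17.5 pools 2 and 3, and at most 0.392 in E14.5 pools. The stage itself stays open, untested apart from these.

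E16.5 pools stood apart from E17.5 pools in 202 genes, among them Sh3d19 and Prmt1, which had fallen before. The day as the whole cause was argued against: 200 genes chosen between E16.5 pool 2 on day 3 and E17.5 pool 1 on day 1 kept a median difference of 0.47 between the other pools on day 2 (0.819 where chosen, and up to 0.14 in nearly all random sets), with 95% of the same sign. E16.5 pool 1, whose dye-swapped arrays correlated least, was argued against as the sole source, since 200 genes chosen there kept 0.333 in pools 2 and 3 (0.908 where chosen), with 79.5% of the same sign. An effect on single probes stays open: other probes of a gene showed a share of 0.665 of the difference, against 0.696 for P30 minus P7. A change of the tissue between the 2 days of gestation stays open as well, untested.

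P7 pool 1 stood apart from P7 pools 2 and 3. The day was argued against, as the Cy3 array of pool 2 correlated better with pool 3 of another day (0.88) than with pool 1 of its own (0.705), a difference of 0.175. An age nearer to a neighbouring stage stays open: the deviation of pool 1 correlated at 0.515 with the direction of E17.5 and at 0.257 with that of P30, values that share the P7 pools, and at 0.1 with the difference between E17.5 and P30. More muscle and less of other tissue in the pool stays open too: skeletal and smooth muscle genes were a median of 0.396 and 0.397 above pools 2 and 3, and prostate secretory (-0.408) and seminal vesicle, vas and duct genes (-0.664), which share members, were below. Luminal epithelium genes did not go with them (-0.02), and cell cycle (0.555), androgen response (0.346), extracellular matrix (0.313) and ER and secretory pathway genes (0.187) were higher as well.

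Other groupings of the pools were tried for each comparison. Between 2 stages there are 10 splits of 6 pools, too few for a share under 0.05, and the real split was in each case the 1 with the most genes. The highest other split called 0 genes by limma in 8 of the 11 comparisons, 2 for E16.5 minus E15.5 (real value 18), 1 for P7 minus E17.5 (654) and 11 for P90 minus P30 (686). The real values of the 8 were 33, 181, 33, 1303, 1965 and 2269 for E15.5 to P90 against E14.5, 202 for E17.5 minus E16.5 and 1396 for P30 minus P7. Across stages, 1 of 100 groupings gave as many genes, the real one (3092, highest other 17). Likewise 1 of 100 gave as many list calls with an estimated correlation (54, highest other 3). Mixed groups take the differences between stages into their spread, which lowers their counts, also in the splits of 6 pools. Regrouping also breaks the tie of stage to day and print set. So these counts show that the real groups called most, and do not set stage apart from day. With the preset correlation 3 of 100 gave as many list calls (130), a share under 0.05. Random groupings gave a median of 92 and up to 145 there. Groups mixed at random also differ in their make-up by stage, so these values are not a rate by chance. Single preset calls are not set apart from chance by this count.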
